A study of Mus musculus with 6 samples.

How the data were processed

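MicroRNAs were measured by small-RNA sequencing in whole thymus of C57BL mice aged 5 weeks. The labels describe n = 3 mice per group as the replicates. Irradiated mice received 6 Gy of X-rays at 800 cGy/min from a distance of 40 cm, and the thymus was collected 24 h later. Control mice were not irradiated. The labels name TRIzol extraction and NEBNext library kits, and they call the molecule polyA RNA. The aligner, the counting tool and the genome build behind the counts are not given in the sources used here.

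The deposited table holds, per the file headers, whole-number read counts for each mature miRNA in each of the 6 libraries. The authors' TPM values were each read count divided by the library's column total and scaled so that each library sums to the same fixed total, with no length term, and recomputed values differed by at most 4.61e-05. The deposited table also gives the authors' log2 fold change of irradiated over control. Its p-value columns hold the authors' p-value and adjusted p-value for the same comparison, and the submitters' notes name DESeq2 1.10.1 among their tools. The counts were used here. A further 6 count columns that the labels do not describe were not used here.

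The table lists 1390 miRNAs, of which 1319 are known and 71 are predicted, and 146 had no count in the 6 libraries. Library totals ranged from 7730641 to 9287017 counts, with 828 to 924 miRNAs counted per library. Predicted miRNAs held 0.001% to 0.003% of the counts. A count of 0 allows a level of up to 3 counts, which is 0.323 to 0.388 CPM (counts scaled to a fixed library total, the same unit as the authors' TPM) depending on the library. This limit covers counting error only, because the reads carry no molecular identifiers. No pair of replicate libraries was a copy of another. Of the known miRNAs, 1274 were matched by precursor sequence to GENCODE M21 (GRCm38), which gave coordinates and host genes.

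Counts were tested with edgeR 4.0.16 in R 4.3.3, using trimmed-mean (TMM) factors, filterByExpr at its defaults and the robust quasi-likelihood test of irradiated against control. Adjusted p-values are Benjamini-Hochberg values over all tested miRNAs, and the threshold was an adjusted p of 0.05 with no fold minimum. Each edgeR adjusted p comes from this test. Levels are TMM-scaled CPM, given as mean ± SD over n = 3 mice, and log2 fold changes are irradiated over control with their SE. The TMM factors ranged from 0.823 to 1.39, both in control libraries. The tested miRNAs held at least 99.97% of each library's counts.

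The tests, the 15 lists of miRNAs, the alternatives and the rule for naming miRNAs were fixed before the data were examined. The lists came from general knowledge. Those reported were p53-linked, miR-17-92 and its paralogous clusters, lymphoid and pan-haematopoietic, stromal and vascular, epithelial, erythroid, myeloid, muscle, remote tissues, inflammation-linked, let-7, miR-15/16 with miR-29, the Dlk1-Dio3 cluster and the Sfmbt2 cluster. The remaining list, which took part in the adjustment, is not reported here. Each list was tested with limma 3.58.1 camera on log2 CPM with prior count 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The same test was run with the correlation estimated from the data. It was also run as fry, which tests whether the miRNAs of a list move, on balance, one way and does not compare them with other miRNAs. Shares of library counts were compared by exact two-sided permutation tests, for which 3 against 3 libraries allow no p under 0.1.

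Named miRNAs were the 12 higher and 12 lower with the largest change among those past the threshold, with a mean of at least 10 CPM and groups that did not overlap. The 3 most abundant miRNAs, up to 4 of the most abundant members of each list, and 5 fixed miRNAs (miR-34a-5p, miR-34c-5p, miR-181a-5p, miR-21a-5p and miR-205-5p) were added. This gave 76 miRNAs. The text also names miR-34b-5p, miR-150-5p, miR-181a-2-3p, miR-145a-5p, miR-126a-5p, miR-200c-3p, miR-141-3p, miR-429-3p, miR-466i-5p, miR-378a-3p, miR-365-3p, miR-128-1-5p, miR-128-2-5p and further members of short counts, all chosen after their values were seen. Those were not recomputed singly under the alternatives.

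Alternatives were other scaling factors (median-of-ratios, library totals, upper quartile), no low-count filter, a mean of at least 10 CPM, DESeq2 1.42.0, limma-voom, a 2-fold minimum, an adjusted p of 0.01, the replicate number as a block, leaving out the most abundant miRNA, known miRNAs only, and leaving out each library in turn. For the lists, an estimated correlation, fry and a prior count of 0.5 were added. Leaving out irradiated replicates 2 and 3 together, leaving out miRNAs that share reads with another, and the differences between miRNA groups within a library were chosen after seeing the data. Without irradiated replicates 2 and 3, a single irradiated library is compared with 3 controls, its spread is assumed to equal that of the controls, and passing or not passing then says little. Some reads that match a miRNA and the reverse complement of another appear to have been counted under both. Among pairs with at least 18 shared bases and at least 60 counts for 1 of the pair, 15 of 31 reverse-complement pairs and 6 of 52 same-strand pairs had counts within 5% of each other. Only miRNAs with such near-equal counts are said here to share reads.

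The procedure was tested on simulated data with 3 against 3 libraries. Of 501 miRNAs tested, 53.7% of 95 changed 2-fold and 96.8% of 95 changed 4-fold were recovered, and 4.67% of the calls had no simulated change. The simulated changes were drawn in equal numbers up and down, and the spread was set alike in both groups. In the data some changes were larger than 4-fold, and the irradiated libraries correlated less with each other than the controls did. The 4.67% therefore need not hold for the real calls.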

Results

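The series title concerns competing RNAs in the irradiated mouse thymus. The thymus is the organ in which T cells mature, and most of its cells are immature lymphocytes (thymocytes) held in a framework of epithelial cells, fibroblasts and blood vessels. Thymocytes are among the most radiation-sensitive cells of the body. MicroRNAs are short RNAs that lower the output of their target messenger RNAs, and many are made mainly in 1 cell type.

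The miRNA content of the thymus differed widely between irradiated and control mice 24 h after 6 Gy. Of the miRNAs listed beforehand as lymphoid 8 of 9 were lower, and of the miR-17-92 list 13 of 13. Of those listed as stromal and vascular 11 of 14 were higher, and of those listed as epithelial 4 of 7. The tests of these 4 lists against other miRNAs passed with a preset correlation but not with an estimated one. Of 519 miRNAs tested, 318 passed the threshold in edgeR, with 144 higher and 174 lower after irradiation. At least 2-fold changes were seen for 124 of the higher and 155 of the lower miRNAs. The control and irradiated values did not overlap for 356 of the 519 miRNAs, where chance gives 10% for 3 against 3, and for 307 of the 318. The correlation of log2 levels across miRNAs, which are not independent replicates, was 0.989 to 0.994 within control, 0.959 to 0.979 within irradiated and 0.850 to 0.908 between groups. Of the 5 predicted miRNAs tested, 1 passed.

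The split between higher and lower depended on the scaling. The median log2 change of all tested miRNAs was 0.01 with TMM factors, 0.12 with median-of-ratios factors, −0.13 with library totals and 0.44 with upper-quartile factors. The upper-quartile factors gave 206 higher and 139 lower miRNAs (59.7% higher) and library totals gave 106 higher and 170 lower (38.4% higher), against 45.3% higher with TMM. The authors' deposited adjusted p-values pass 0.05 for 325 miRNAs, 160 higher and 165 lower. These include 291 of the 318, and all 318 had the same sign in the authors' table. The authors' values come from the same libraries, so the shared signs are not independent support. DESeq2 as run here gave the same numbers (325, 160 higher and 165 lower), so it and the authors' result are not separate checks.

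**Figure D1:**
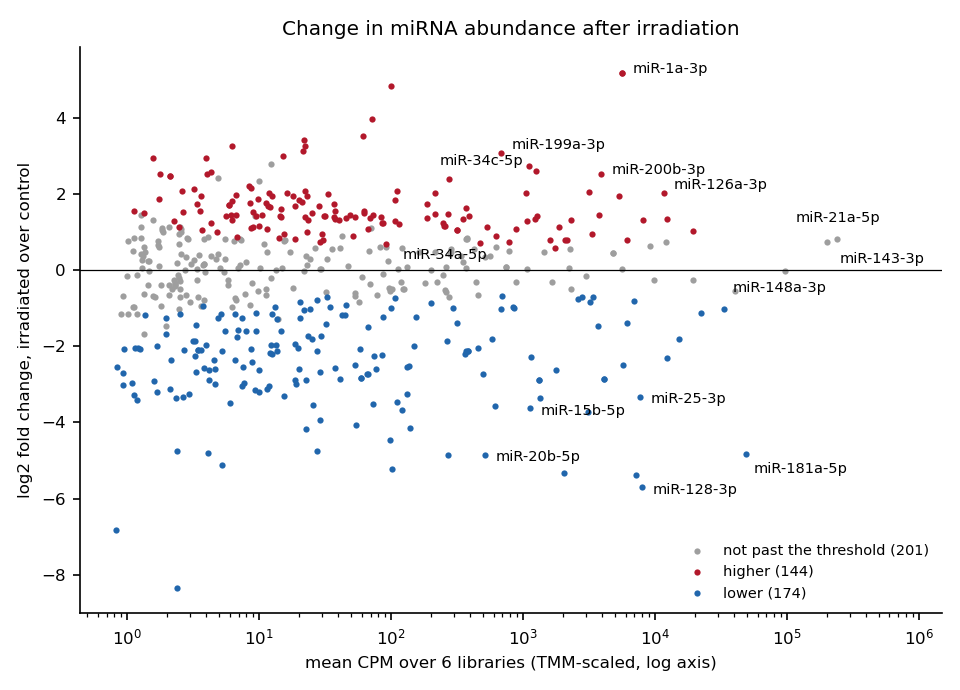
Log2 fold change of irradiated over control (vertical axis) against mean TMM-scaled CPM over the 6 libraries (horizontal log axis), 1 point per tested miRNA, coloured by whether it passed the edgeR threshold as higher or lower. The 144 higher and 174 lower miRNAs include none of the 3 most abundant (miR-21a-5p, miR-143-3p and miR-148a-3p), with miR-1a-3p at 5.19 and miR-128-3p at −5.70.

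A few miRNAs made up most of each library. The 10 most abundant miRNAs held 65.8% to 81.6% of the counts. The most abundant by mean level was miR-21a-5p, followed by miR-143-3p, a miRNA of smooth muscle and fibroblasts, and miR-148a-3p. The share of miR-21a-5p was 17.4% ± 0.668 (SD, n = 3) in control and 29.2% ± 7.99 (SD, n = 3) in irradiated libraries. The lymphoid list went from 13.4% ± 1.92 to 0.864% ± 0.177 of all counts (SD, n = 3 per group). The let-7 family went from 15.05% ± 1.40 to 8.30% ± 0.986, and the miR-17-92 list from 3.24% ± 0.346 to 0.324% ± 0.0379. The stromal and vascular list went from 16.7% ± 3.51 to 29.4% ± 5.73 and the epithelial list from 1.23% ± 0.174 to 2.48% ± 0.417. Each of these 6 shares had an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. Most of the stromal and vascular share, and of its difference, was miR-143-3p, with 14.8% ± 3.83 in control and 24.0% ± 5.17 in irradiated libraries (SD, n = 3, exact permutation p of 0.2). The other members of that list held 1.89% ± 0.354 and 5.39% ± 1.11 (SD, n = 3, exact permutation p of 0.1).

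**Figure D2:**
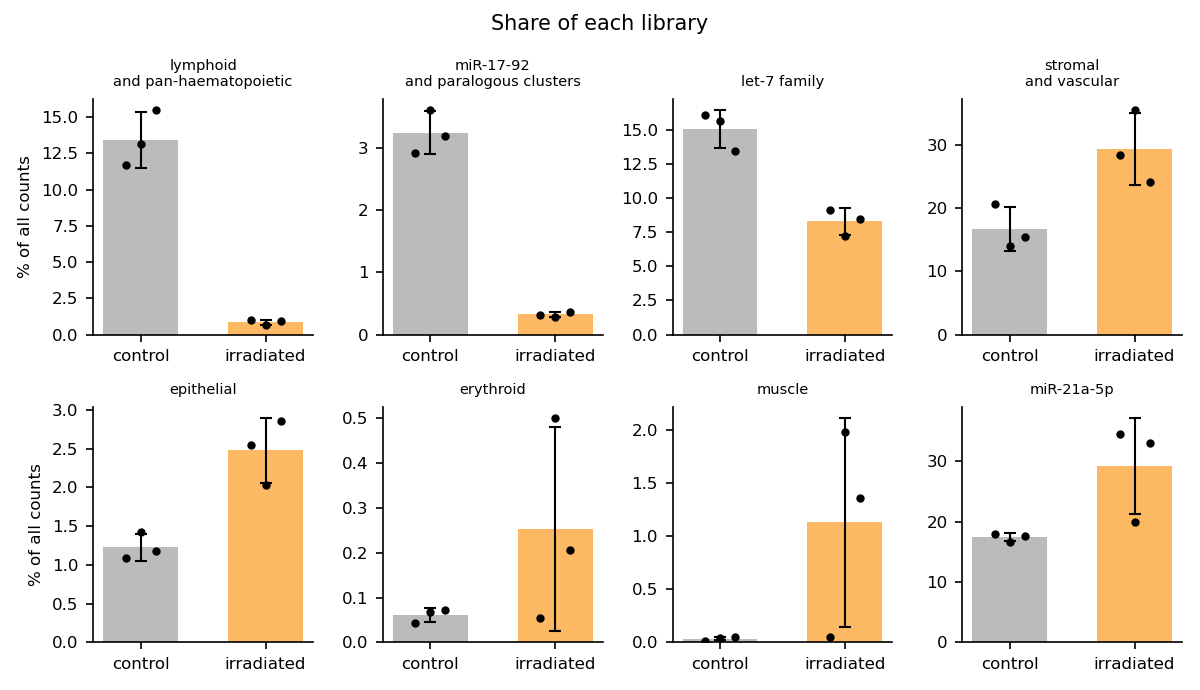
Share of all counts (%) held by 7 miRNA lists and by miR-21a-5p in control and irradiated libraries, with bars for the mean, error bars for the SD (n = 3) and points for single libraries. The lymphoid share was 13.4% in control and 0.864% in irradiated libraries, and the erythroid and muscle shares were spread widely among the irradiated libraries.

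Thymocytes carry large amounts of the miR-181 family, which tunes the response of immature T cells to their antigen receptor, and of miR-128, whose gene lies in an intron of the thymocyte gene Arpp21. These miRNAs were among those with the largest decreases. MiR-181a-5p fell from 94375 ± 29176 to 3325 ± 1046 CPM, a log2 fold change of −4.83 ± 0.39 (SE), with an edgeR adjusted p of 1.8e-05. MiR-181b-5p changed by −5.39 ± 0.32 (SE) and miR-181a-1-3p by −5.32 ± 0.32, each with an edgeR adjusted p of 3.1e-06. MiR-128-3p had the largest change of all that met the naming rule, −5.70 ± 0.36 (SE), from 15623 to 300 CPM (299.5 ± 96.8 in irradiated libraries), with an edgeR adjusted p of 4.0e-06. All 3 irradiated libraries lay below all 3 control libraries for each of these.

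MiR-181a and miR-181b are made from 2 pairs of precursors. One pair lies on chromosome 1 in GRCm38 (Mir181a-1 at 137966455 to 137966541 and Mir181b-1 at 137966639 to 137966718). The other lies on chromosome 2 (Mir181a-2 at 38852735 to 38852810), antisense to Nr6a1. Their passenger strands differ in sequence and report on each locus. MiR-181a-1-3p fell further than miR-181a-2-3p (−2.08), by −3.23 on the log2 scale within libraries (95% interval −4.02 to −2.44). The limma adjusted p over 8 such differences was 1.1e-04, and it passed with any 1 library left out. MiR-181b-1-3p changed by −4.08 ± 0.44 (SE). Mir128-2 lies on chromosome 9 at 112118636 to 112118711 in the Arpp21 intron, and Mir128-1 on chromosome 1 at 128202361 to 128202430 in an intron of R3hdm1. The strand specific to the Arpp21 locus, miR-128-2-5p, was at 10.3 ± 2.27 CPM in control and at 0.913, 0 and 0 CPM in irradiated replicates 1, 2 and 3 (edgeR adjusted p of 6.1e-04). That specific to the R3hdm1 locus, miR-128-1-5p, was near the detection limit at 1.87 CPM in control and fell by 2.05 on the log2 scale.

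The lymphoid and pan-haematopoietic list had 9 tested members. Of these, 8 were lower, 0 were higher and 1 did not pass, and 8 were lower adjusted over the list alone. The median log2 change was −3.45 with a camera adjusted p of 2.1e-04, and adjusted p = 0.4662 with an estimated correlation. MiR-142a, made in all blood cells, has its gene on chromosome 11 at 87756864 to 87756927. MiR-142a-3p fell from 7195 ± 799.8 to 993 ± 43.2 CPM and miR-142a-5p by 1.39 on the log2 scale. With replicate 1 as the only irradiated library miR-142a-5p did not pass (−0.80, edgeR adjusted p of 0.0763, within 4.9e-05 to 0.0763 over its 18 alternatives). The member that did not pass was miR-150-5p, a miRNA of mature lymphocytes, at −0.31 (edgeR adjusted p of 0.373).

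The miR-17-92 cluster and its 2 paralogues promote proliferation and survival of lymphocytes. All 13 tested members of this list were lower after irradiation, and 13 were lower adjusted over the list alone. The median log2 change was −3.52 with a camera adjusted p of 6.1e-06, and adjusted p = 0.4662 with an estimated correlation. The most abundant member, miR-25-3p, has its gene on chromosome 5 at 138165321 to 138165404 in the cell-cycle gene Mcm7. It fell from 14069 to 1403 CPM (−3.33 ± 0.28 SE, edgeR adjusted p of 1.8e-05). MiR-92a-3p fell by 3.74, miR-19b-3p by 3.35 and miR-93-5p by 2.63 on the log2 scale.

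The X-linked paralogue fell further than miR-17-92 itself. This cluster runs from Mir363 (start 52741693) to Mir106a (end 52742567) on chromosome X. MiR-18b-5p changed by −5.22 ± 0.89 (SE), from 197 to 5.33 CPM, with an edgeR adjusted p of 0.0021. The value of miR-18b-5p was −4.51 without irradiated replicate 2 and −6.73 without irradiated replicate 1. MiR-20b-5p and miR-363-3p each changed by −4.86, miR-363-5p by −4.18 and miR-106a-5p by −4.15. MiR-106a-5p changed by −3.54 without irradiated replicate 2. Within libraries the X-linked cluster fell further than the miR-17-92 cluster by −2.12 on the log2 scale (95% interval −2.93 to −1.31, limma adjusted p of 0.0012). It passed with any 1 library left out. The third cluster, miR-106b-25, did not differ detectably from miR-17-92 (−0.01, 95% interval −0.64 to 0.62). Several mature miRNAs of the clusters differ by only a few bases, which limits how exactly reads can be assigned among them. Genes of miR-92a-3p (Mir92-2) and miR-19b-3p (Mir19b-2) also lie in the X-linked cluster, so their reads do not report on a single cluster.

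Among other miRNAs named for large decreases, miR-130b-5p changed by −4.46 ± 0.34 (SE) and miR-298-5p by −4.76 ± 0.69. MiR-298-5p changed by −4.06 without irradiated replicate 2 and by −6.07 without irradiated replicate 1.

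The Sfmbt2 cluster is a rodent-specific array of related miRNAs (miR-297, miR-466, miR-467 and miR-669) in an intron of the Polycomb gene Sfmbt2 on chromosome 2. The list tested here holds every miRNA with these names, whatever its position. It was lower almost throughout. Of 48 tested members of 67 in the table, 47 were lower and 1 (miR-466i-5p) did not pass, and 47 were lower adjusted over the list alone. The median log2 change was −2.64 with a camera adjusted p of 6.3e-15, and adjusted p = 0.4662 with an estimated correlation. MiR-467a-5p, with 1 of its genes at 10476346 to 10476418, fell from 2320 ± 386 to 314 ± 95.8 CPM. MiR-669a-5p changed by −2.52 and miR-467e-5p by −2.55. Members share near-identical sequences, and miR-467a-5p and miR-467b-5p had identical counts, so the 48 are not independent measurements.

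The let-7 family is abundant in most differentiated tissues. Of 9 tested members, 1 was higher, 5 were lower and 3 did not pass, and 1 was higher and 5 lower adjusted over the list alone. The list itself did not pass (median −0.80, camera adjusted p of 0.331). Let-7g-5p fell by 1.13 (edgeR adjusted p of 0.0054) and let-7i-5p by 1.02 (0.0169) on the log2 scale, and let-7e-5p rose by 1.34. Let-7f-5p (−0.55) and let-7c-5p (−0.27) did not pass. The calls for let-7g-5p and let-7i-5p depended on single libraries. Without control replicate 1 the edgeR adjusted p was 0.0523 for let-7g-5p, which ranged from 7.7e-05 to 0.108 over its 18 alternatives. For let-7i-5p the edgeR adjusted p was 0.169 without control replicate 1, 0.0765 without control replicate 3, 0.118 without irradiated replicate 2 and 0.112 without irradiated replicate 3, within 2.3e-04 to 0.373 over its alternatives. With upper-quartile factors neither passed.

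The miR-15/16 and miR-29 families restrain the cell cycle and the extracellular matrix, respectively, and their members moved apart. Of 10 tested members, 4 were higher, 4 were lower and 2 did not pass, and 4 were higher and 5 lower adjusted over the list alone. The median (−0.10) and the mean (−0.43) were negative while camera gave an upward direction (adjusted p of 0.955) and fry a downward one (adjusted p of 0.0512). MiR-15b-5p, with its gene in an intron of Smc4 on chromosome 3 (Mir15b at 69009772 to 69009835), fell by 3.63 on the log2 scale. MiR-16-5p, with 1 of its genes also in Smc4 (Mir16-2 at 69009902 to 69009996), fell by 2.48. MiR-195a-5p rose by 1.304 and miR-497a-5p by 1.95. MiR-29a-3p rose by 0.60 (edgeR adjusted p of 0.0376), and miR-29b-3p did not pass (0.47), though it did without irradiated replicate 2 (0.0414, within 0.0035 to 0.581 over its alternatives). The call for miR-29a-3p was lost without control replicate 1 (0.0718), 2 (0.129) or 3 (0.0925) or without irradiated replicate 3 (0.105), within 0.0047 to 0.225 over its 18 alternatives.

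**Figure D3:**
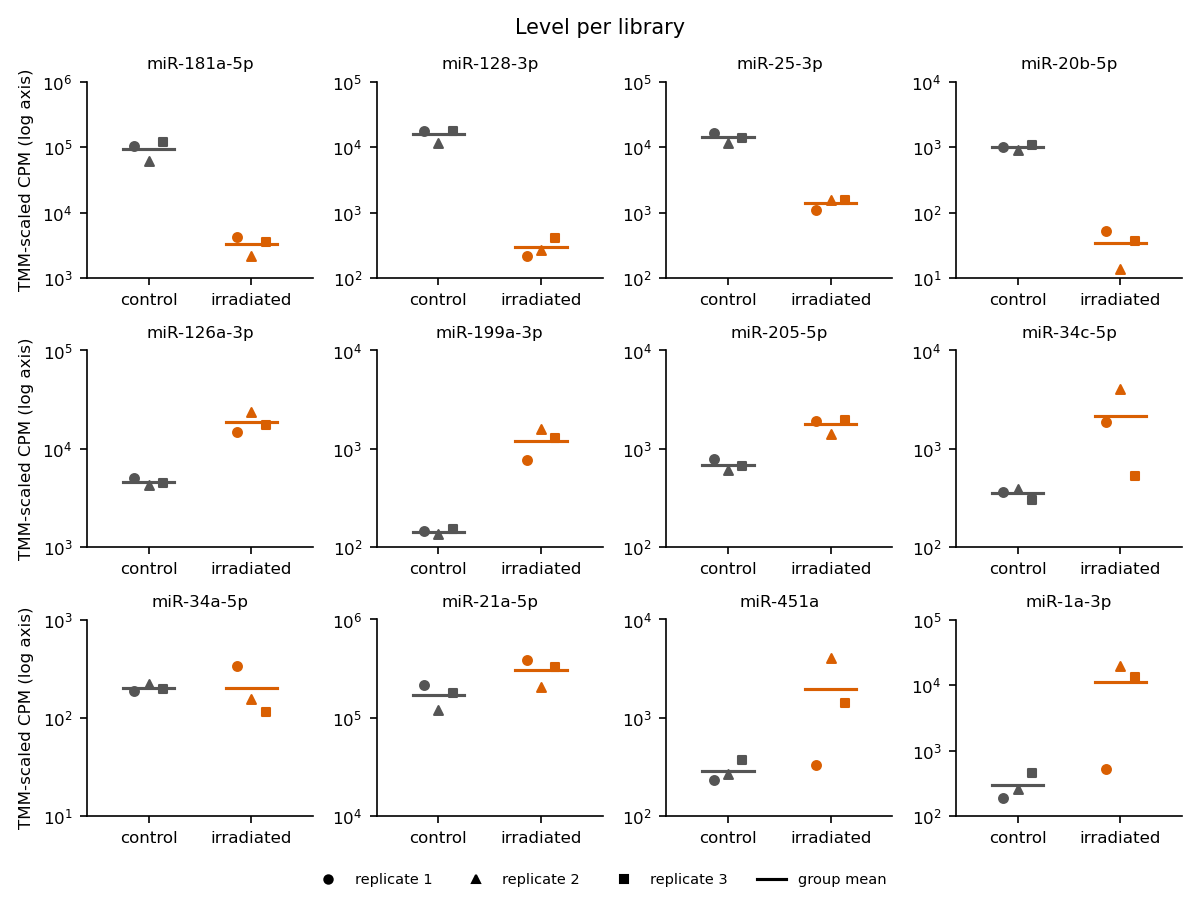
TMM-scaled CPM (log axis) of 12 miRNAs in the control and irradiated libraries, with a marker shape for each replicate number and a line at the group mean. MiR-181a-5p and miR-128-3p are lower in all 3 irradiated libraries and miR-126a-3p and miR-205-5p higher, while miR-1a-3p is far higher in irradiated replicates 2 and 3 (19377 and 13225 CPM) than in replicate 1 (527 CPM).

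Blood vessels and connective tissue carry their own miRNAs, and most of those listed were higher after irradiation, though not the most abundant, miR-143-3p. MiR-126a-3p comes from endothelial cells and lies within Egfl7 on chromosome 2 at 26591357 to 26591429. It rose from 4615 ± 367 to 18702 ± 4514 CPM (2.02 ± 0.26 SE, edgeR adjusted p of 1.5e-04). The other strand of the same precursor, miR-126a-5p, changed by 0.09 on the log2 scale and did not pass. MiR-199a-3p, a fibroblast miRNA with 1 of its genes in Dnm3os on chromosome 1 at 162217814 to 162217923, rose from 145 ± 8.21 to 1217 ± 414 CPM (3.07 ± 0.32 SE, edgeR adjusted p of 5.2e-05). MiR-99a-5p rose by 1.96 and miR-100-5p by 1.33. Of 14 tested members of the stromal and vascular list, 11 were higher, 0 were lower and 3 did not pass (miR-143-3p, miR-145a-5p and miR-126a-5p), and 11 were higher adjusted over the list alone. The median was 1.47 with a camera adjusted p of 7.9e-05, and adjusted p = 0.4662 with an estimated correlation. MiR-143-3p, at 151488 ± 74986 CPM in control and 251202 ± 58886 in irradiated libraries, changed by 0.73 (edgeR adjusted p of 0.118). It passed without control replicate 1 (1.26, adjusted p of 0.0190, within 0.0074 to 0.305 over its alternatives).

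Epithelial cells form the thymic framework that selects T cells, and some of their miRNAs were higher too. MiR-205-5p, a miRNA of thymic epithelium and of stratified epithelia on chromosome 1 at 193507463 to 193507530, rose from 693 ± 88.1 to 1776 ± 317 CPM (1.36 ± 0.25 SE, edgeR adjusted p of 0.0012). MiR-200b-3p, on chromosome 4 at 156055681 to 156055750, rose from 1154 ± 428 to 6693 ± 2251 CPM (2.54 ± 0.35 SE, edgeR adjusted p of 2.0e-04). MiR-203-3p rose by 1.32 and miR-200c-3p by 2.02. Of 7 tested members, 4 were higher, 0 were lower and 3 did not pass (miR-200a-3p, miR-141-3p and miR-429-3p), and 5 were higher adjusted over the list alone. The list median was 1.32 with a camera adjusted p of 0.0130, and adjusted p = 0.496 with an estimated correlation. Without irradiated replicate 1 the camera adjusted p was 0.0882, within 0.0015 to 0.496 over its 19 alternatives. MiR-200a-3p (0.63, edgeR adjusted p of 0.0515) passed without irradiated replicate 2 (0.97, adjusted p of 0.0103, within 0.00999 to 0.190). The epithelial and stromal lists did not differ detectably in their change (−0.22, 95% interval −1.01 to 0.58).

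The Dlk1-Dio3 region on chromosome 12 is an imprinted locus whose maternal copy carries one of the largest mouse miRNA clusters, active in embryonic and connective tissue. Most of its tested miRNAs were higher after irradiation. Of 34 members in the table, 21 were tested, 15 were higher, 0 were lower and 6 did not pass, and 15 were higher adjusted over the list alone. The median log2 change was 1.76 with a camera adjusted p of 2.4e-05, and adjusted p = 0.496 with an estimated correlation. MiR-379-5p, at 109709060 to 109709125, rose from 87.3 ± 28.3 to 464 ± 135 CPM (2.41 ± 0.35 SE, edgeR adjusted p of 2.7e-04). MiR-434-3p rose by 2.09, miR-381-3p by 1.86, miR-411-5p by 1.47 and miR-127-3p by 1.37. Each of these 5 was highest in irradiated replicate 2, as with miR-434-3p at 21.8, 60.4 and 26.5 CPM in irradiated replicates 1, 2 and 3. Replicate 2 was also the library highest in the muscle miRNA miR-1a-3p (19377 CPM) and the red-cell miRNA miR-451a (4095 CPM). Without that replicate the list median was 1.55, and without irradiated replicates 2 and 3 it was 1.31. The change did not differ detectably from that of the stromal list (0.07, 95% interval −0.68 to 0.82).

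Ionizing radiation activates the transcription factor p53, and the miR-34 family is among its best-known miRNA targets. Its members behaved differently at 24 h. MiR-34b and miR-34c, on chromosome 9 at 51103562 to 51103645 and 51103034 to 51103110, rose. MiR-34a, on chromosome 4 at 150068454 to 150068555, did not pass. MiR-34b-3p rose from 3.66 ± 0.701 to 39.9 ± 36.7 CPM (3.44 ± 0.65 SE, edgeR adjusted p of 0.0018) and miR-34c-3p by 3.14 ± 0.65 (SE). The most abundant, miR-34c-5p, rose from 354 ± 47.4 to 2147 ± 1778 CPM (2.60 ± 0.66 SE, edgeR adjusted p of 0.0114), with 1865, 4050 and 527 CPM in irradiated replicates 1, 2 and 3. Without irradiated replicate 2 the log2 changes were 2.58, 2.41 and 1.95, and all 3 passed the 0.05 threshold under each of their 18 alternatives. At an adjusted p of 0.01 miR-34c-5p did not pass. MiR-34b-5p did not pass (2.43, edgeR adjusted p of 0.0627).

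MiR-34a-5p was at 202 ± 16.1 CPM in control and 203 ± 119 CPM in irradiated libraries (0.01 ± 0.38 SE, edgeR adjusted p of 0.980). The irradiated libraries lay at 338, 156 and 115 CPM, so the mean covers libraries on both sides of control. With replicate 1 as the only irradiated library the change was 0.94, which rests on 1 sample. Within libraries the change of miR-34b and miR-34c minus miR-34a was 2.74 (95% interval 1.31 to 4.18, limma adjusted p of 0.0060). Without control replicate 1 this difference was 2.72 with an adjusted p of 0.0602. Of 8 tested members of the p53-linked list, 3 were higher, 0 were lower and 5 did not pass, and 3 were higher adjusted over the list alone. The list did not pass (median 1.49, camera adjusted p of 0.186). MiR-192-5p (−0.32), miR-194-5p (−0.56) and miR-215-5p (0.55) did not pass. MiR-194-5p passed without irradiated replicate 1 (adjusted p of 0.0284, within 0.0284 to 0.961), and miR-215-5p without irradiated replicate 2 (0.0124, within 2.9e-05 to 0.561).

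MiR-21, miR-146 and miR-155 respond to inflammatory signals. MiR-146a-5p rose from 623 ± 96.6 to 1538 ± 542 CPM (1.304 ± 0.29 SE, edgeR adjusted p of 0.0040). MiR-146b-5p rose by 0.78 (edgeR adjusted p of 0.0342) but did not pass without control replicate 1 (0.115), control replicate 2 (0.118) or irradiated replicate 3 (0.122), the last being the highest over its alternatives and 0.0031 the lowest. MiR-21a-5p, whose gene overlaps an exon of Vmp1 on chromosome 11 at 86584067 to 86584158, changed by 0.83 ± 0.34 (SE), from 172130 to 306747 CPM. The edgeR adjusted p of miR-21a-5p was 0.0522, over the threshold, and the groups overlapped. It passed under 8 of 17 alternatives, with an adjusted p from 0.0031 to 0.187. These included leaving out control replicate 1 (1.16, 0.0454) or irradiated replicate 2 (1.26, 0.0107). MiR-155-5p did not pass (−0.12), and its other strand, miR-155-3p, fell by 1.45. Of 8 tested members of the inflammation-linked list, 3 were higher, 1 was lower and 4 did not pass, and 1 was higher and 1 lower adjusted over the list alone. The list did not pass (median 0.33, camera adjusted p of 0.508).

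The muscle miRNAs miR-1a-3p, miR-133a-3p and miR-206-3p had the largest increases among named miRNAs, and the libraries contributed unequally. MiR-1a-3p was at 303 ± 139 CPM in control and at 527, 19377 and 13225 CPM in irradiated replicates 1, 2 and 3 (5.19 ± 1.24 SE, edgeR adjusted p of 0.0101). MiR-1b-5p, the reverse complement of miR-1a-3p, had nearly the same counts. MiR-133a-3p changed by 4.85 and was also highest in replicates 2 and 3 (13.8, 419 and 146 CPM in irradiated replicates 1, 2 and 3). MiR-206-3p changed by 3.97 and was higher in replicate 1 than in replicate 3 (61.2, 320 and 24.1 CPM). Without irradiated replicate 2, miR-1a-3p did not pass (0.0624, within 7.9e-09 to 0.0925 over its 18 alternatives), and miR-133a-3p and miR-206-3p changed by 3.81 and 2.52. MiR-133a-3p did not pass without control replicate 3 (0.0556, within 1.8e-08 to 0.0932). MiR-206-3p did not pass without control replicate 2 (0.0502), control replicate 3 (0.0586) or irradiated replicate 1 (0.0507), within 2.7e-20 to 0.116. MiR-193b-3p was highest in replicate 2, with 9, 54.1 and 17.3 CPM in irradiated replicates 1, 2 and 3 (2.99, and 2.19 without irradiated replicate 2). Of 4 tested members of the muscle list, 3 were higher, 0 were lower and 1 (miR-499-5p) did not pass, and 3 were higher adjusted over the list alone. The list did not pass (median 4.41, camera adjusted p of 0.0836). It passed without control replicate 1 (0.0245), 2 (0.0244) or 3 (0.0181) or irradiated replicate 1 (3.2e-04), with library totals (0.0397) and with no low-count filter (0.0032), within 3.2e-04 to 0.496 over its 19 alternatives. MiR-499-5p passed without irradiated replicate 1 (0.0125, within 0.0090 to 0.633).

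Red-cell miRNAs were also highest in irradiated replicates 2 and 3. MiR-451a, on chromosome 11 at 78073170 to 78073241, was at 292 ± 73.3 CPM in control and at 335, 4095 and 1411 CPM in irradiated replicates 1, 2 and 3 (2.74 ± 0.83 SE, edgeR adjusted p of 0.0264). MiR-144-3p changed by 3.53 and miR-144-5p by 3.28. MiR-451a changed by 1.80 and miR-144-3p by 2.87 without irradiated replicate 2, and with replicate 1 as the only irradiated library the changes were 0.41 and 0.12. Each of the 3 lost its call without control replicate 1 (0.0718, 0.0611 and 0.0718 for miR-451a, miR-144-3p and miR-144-5p), control replicate 2 (0.0771, 0.0626 and 0.0765) or control replicate 3 (0.0743, 0.0804 and 0.0665). MiR-144-5p also lost it without irradiated replicate 2 (0.0563). Over 18 alternatives the edgeR adjusted p reached 0.220, 0.801 and 0.904, with lowest values of 1.0e-06, 2.8e-08 and 1.5e-07. Of 4 tested members of the erythroid list, 3 were higher, 0 were lower and 1 (miR-486a-5p) did not pass, and 3 were higher adjusted over the list alone. The list did not pass (median 3.01, camera adjusted p of 0.141), but did without irradiated replicate 1 (0.0102, within 0.0102 to 0.580). MiR-486a-5p also passed without irradiated replicate 1 (0.0027, within 0.0027 to 0.679). The erythroid share was 0.0607% ± 0.0160 of counts in control and 0.253% ± 0.227 in irradiated libraries (SD, n = 3, exact permutation p of 0.3). The muscle share was 0.0346% ± 0.0159 and 1.13% ± 0.984 (SD, n = 3, exact permutation p of 0.1). With replicates 2 and 3 both left out, 321 miRNAs passed, 260 of them among the 318, in a fit with 1 irradiated library whose spread is assumed to equal that of the controls.

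MicroRNAs of myeloid cells, such as granulocytes and macrophages, made up the next list. Of its 4 tested members, 1 was higher, 0 were lower and 3 did not pass, and 1 was higher adjusted over the list alone. The list did not pass (median 0.79, camera adjusted p of 0.141). MiR-223-5p rose by 1.99 (edgeR adjusted p of 0.0014). MiR-223-3p did not pass (0.59), but did without irradiated replicate 1 (0.0104, within 0.0022 to 0.943 over its alternatives). MiR-511-3p and miR-511-5p did not pass, and the former did without irradiated replicate 2 (0.0379, within 0.0067 to 0.305).

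MicroRNAs of tissues remote from the thymus were listed as a background, but they were not all low. In control libraries miR-375-3p was at 1068 ± 249 CPM and miR-9-5p at 157 ± 29.1 CPM. Of 4 tested members, 2 were higher, 0 were lower and 2 did not pass, and 2 were higher adjusted over the list alone (median 0.79, camera adjusted p of 0.186). The liver miRNA miR-122-5p was near the detection limit, at 0.674 ± 0.528 CPM in control and 3.59 ± 1.5 in irradiated libraries (2.47, and 3.27 without control replicate 1). The brain miRNA miR-9-5p rose by 1.17 (edgeR adjusted p of 0.0147), though not with library totals (0.0609, within 4.6e-04 to 0.0609 over its alternatives), and miR-9-3p (0.41) and the endocrine miRNA miR-375-3p (0.03) did not pass.

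Of the 15 lists, 6 passed camera with the preset correlation. None of the 6 passed camera with an estimated correlation, where 1 list had an unadjusted p under 0.05, and all 6 passed fry. By camera's preset test, 3 lists were lower (miR-17-92, lymphoid and Sfmbt2) and 3 were higher (stromal, epithelial and Dlk1-Dio3). Other divisions of the 6 libraries into 3 and 3 gave 3 to 9 lists, so the count of 6 lists does not set the real groups apart.

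**Figure D4:**
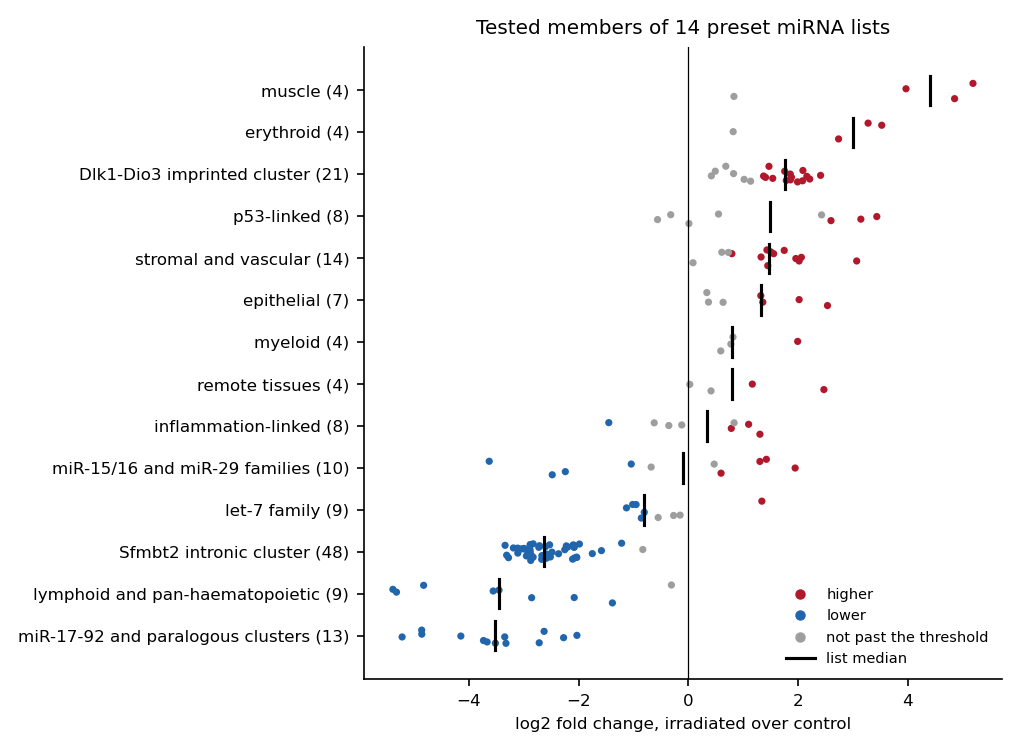
Log2 fold change of irradiated over control (horizontal axis) for each tested member of 14 miRNA lists (vertical axis, with the number tested), coloured by the edgeR call, with a bar at the list median. Medians run from −3.52 for the miR-17-92 list to 4.41 for the muscle list.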

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

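The count of miRNAs past the threshold between irradiated and control libraries was 318. It was 327 with median-of-ratios factors, 276 with library totals, 345 with upper-quartile factors, 344 with no filter, 325 with DESeq2, 312 with limma-voom, 279 with a 2-fold minimum, 228 at an adjusted p of 0.01, 324 without the most abundant miRNA, 321 for known miRNAs, and 266 to 374 with 1 library left out. With a mean of at least 10 CPM it was 210, of which 87 were higher, since 313 rather than 519 miRNAs were tested. At an adjusted p of 0.01, 87 were higher, by construction of the stricter threshold. Of the 57 named miRNAs past the threshold, 44 passed at 0.05 under all of up to 18 alternatives of scaling, filter, tool, block or libraries and miRNAs left out, 13 did not under at least 1, and 0 reversed. Apart from these, 45 of the 57 passed at an adjusted p of 0.01 and 55 changed at least 2-fold. The 13 were miR-1a-3p, miR-1b-5p, miR-133a-3p, miR-206-3p, miR-451a, miR-144-3p, miR-144-5p, miR-9-5p, miR-146b-5p, miR-29a-3p, miR-142a-5p, let-7g-5p and let-7i-5p, of which miR-142a-5p failed only where replicate 1 was the sole irradiated library. With the replicate number as a block, 298 passed, 293 of them among the 318. The samples share only a number. After each miRNA's group mean was subtracted from its log2 levels, the correlations between same-numbered control and irradiated libraries were 0.099, −0.024 and 0.230. By these, 2 of the 3 control libraries correlated best with the irradiated library of their own number. The alternatives planned for normalized values alone were not run, since the table held counts. Leaving out irradiated replicates 2 and 3 together (321 passed, with 1 irradiated library left, so that the controls alone give the spread) and leaving out miRNAs that share reads (299 passed, 298 among the 318) were chosen after seeing the data.

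Of the 6 lists called, 0 passed with an estimated correlation, and the lists past the threshold numbered 6 or 7 with 1 library left out. With library totals 7 passed, the muscle list (0.0397) joining. With no filter 9 passed, the muscle (0.0032), erythroid (0.0493) and remote-tissue (0.0493, within 0.0493 to 0.555 over its alternatives) lists joining. The p53-linked list passed only in the comparison with that 1 irradiated library (0.0083, within 0.0083 to 0.516 over its 19 alternatives). The miR-15/16 and miR-29 list turned in its direction of test with upper-quartile factors (median 0.35), no filter (−0.15), the block (−0.11), without the most abundant miRNA (0.10) and in fry (−0.10), with medians of −0.28 to 0.18 leaving out 1 library. For the let-7 family the direction of the test turned without irradiated replicates 2 and 3 (median −0.40). Without the most abundant miRNA in the denominator, the log2 ratio of shares was −3.09 for the miR-17-92 list, −0.63 for the let-7 list and 1.24 for the epithelial list, against −3.32, −0.86 and 1.01.

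Changes near 0 that were not called turned in sign. For miR-148a-3p the log2 change was 0.10 with median-of-ratios factors, 0.41 with upper-quartile factors, 0.051 with DESeq2, 0.027 with limma-voom, 0.027 with the block, 0.18 without the most abundant miRNA, 0.32 without irradiated replicates 2 and 3, and −0.23 to 0.35 leaving out 1 library. For miR-375-3p it was −0.10 with library totals, −0.031 with no filter, −0.23 with a mean of at least 10 CPM, and −0.15 to 0.32 leaving out 1 library. For miR-34a-5p it was −0.20 with library totals, −0.030 with no filter, −0.24 with a mean of at least 10 CPM, −0.15 with limma-voom, −0.15 with the block, and −0.61 to 0.41 leaving out 1 library. With upper-quartile factors it was 0.12 for miR-192-5p, 0.32 for miR-155-5p and 0.18 for let-7c-5p. For miR-155-5p it was 0.069 without the most abundant miRNA and −0.20 to 0.095 leaving out 1 library. For let-7c-5p it was 0.30 without irradiated replicates 2 and 3 and −0.52 to 0.10 leaving out 1 library. For miR-223-3p it was −1.23 without irradiated replicates 2 and 3, from that 1 library, and −0.044 to 1.06 leaving out 1 library. Among differences within libraries, epithelial list minus stromal list was 0.35 without irradiated replicates 2 and 3 and −0.50 to 0.12 leaving out 1 library. Dlk1-Dio3 list minus stromal list was −0.11 and −0.36 to 0.20, erythroid list minus stromal list −1.13 without both, and miR-106b-25 cluster minus miR-17-92 cluster −0.19 to 0.13 leaving out 1 library. Except where construction is named above, the cause was not tested. With 3 libraries per group, simulated 2-fold changes were recovered for 53.7%, so smaller changes can be missed.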

Other observations

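All tests in this part except those on splits of the libraries were chosen after the result was seen. The mature strands of 1 precursor did not always change alike. Of 68 precursors with both strands tested, the ratio of the strands passed a limma adjusted p of 0.05 for 11, 4 toward the 5p and 7 toward the 3p strand. For 8 of them neither strand had counts within 5% of a miRNA with at least 18 shared bases. These were let-7d, miR-106b, miR-15b, miR-199a, miR-200b, miR-223, miR-27b and miR-28a. The 3p strand of miR-27b still shares 18 bases with miR-27a-3p, at 967946 and 113070 counts over the 6 libraries. For miR-27b the 5p strand gained on the 3p strand by 1.596 on the log2 scale, and for miR-199a the 3p strand gained on the 5p strand, a ratio of −1.61. For miR-126a, whose 5p strand appears to share reads with miR-126b-3p, the 3p strand gained on the 5p strand (ratio −1.92, limma adjusted p of 0.0070). The count was 3, 2 and 0 without control replicates 1, 2 and 3, and 30, 7 and 6 without irradiated replicates 1, 2 and 3. Which ratios passed in each case was not compared.

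Several miRNAs outside the muscle list also lay higher in irradiated replicates 2 and 3. MiR-378a-3p, abundant in muscle and brown fat, was at 22846 and 17280 CPM in these libraries, at 5653 CPM in irradiated replicate 1 and at 7959 to 10068 CPM in control. MiR-365-3p was at 38.3 and 11.2 CPM against 1.04 CPM in irradiated replicate 1 and 2.71 to 4.17 CPM in control.

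The 6 libraries can be divided into 3 and 3 in 10 ways. By edgeR the real division gave 318 miRNAs past the threshold, and the highest of the others gave 0, so 1 of the 10 splits gave as many. All the others mix control and irradiated libraries, so a difference between these groups widens their spread and leaves few calls. Their 0 calls are therefore not a measure of chance. At an unadjusted p of 0.05 the real division gave 345 and the others 0 to 19. The real division gave 6 lists, the highest of the others gave 9, and 7 of the 10 splits gave as many. The other splits gave 3 to 9 lists, so the number of lists does not set the real division apart. The 10 splits are too few for a share under 0.05.

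The first pattern is the high level of muscle miRNAs in irradiated replicates 2 and 3, where miR-1a-3p was 64.0 and 43.7 and miR-133a-3p 62.6 and 21.9 times the control mean, while miR-206-3p was 37.3 and 2.80 times. Muscle tissue taken with the thymus may be a source, and a single kind of muscle would bring these miRNAs in a fixed ratio. In these 2 libraries the log2 ratio of miR-133a-3p to miR-1a-3p differed on average from the other 4 by −0.63 (SD of the other 4 = 0.53). The log2 ratio of miR-206-3p to miR-1a-3p differed on average from the other 4 libraries by −2.82 (2.82 in size, SD of the other 4 = 1.12), but it was −5.92 in replicate 2 and −9.10 in replicate 3, against −5.72 to −3.10 in the other 4, so replicate 3 carries most of it and muscle stays open. A rise caused by irradiation in thymus cells is open too, since irradiated replicate 1 reached 1.74, 2.07 and 7.12 times the control mean for miR-1a-3p, miR-133a-3p and miR-206-3p and 1 library cannot decide. These 2 explanations cannot be told apart here because only 3 irradiated libraries were available and no tissue marker other than miRNAs was used here.

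The second pattern is the decrease of lymphoid miRNAs with the increase of stromal and epithelial miRNAs. Library scaling shifts all miRNAs of a library together, which argues against it as the source of the gap between the lists. Under 4 scalings the lowest stromal median was 1.31 and the lymphoid median stayed at or below −2.98. These scalings moved the median of all tested miRNAs only between −0.13 and 0.44. Neither list could have reached 0 that way, so the 4 scalings say little on the direction of either list. A lower share of thymocytes may explain both, since it would raise the miRNAs of all other cell types alike. The epithelial list minus the stromal list changed by −0.215 (95% interval −1.01 to 0.58), an interval too wide to exclude a difference of 1 on the log2 scale. Members of the stromal list changed by 0.09 to 3.07, the lowest being miR-126a-5p, whose other strand miR-126a-3p rose by 2.02. The list median was 0.79 for myeloid, 3.01 for erythroid and 4.41 for muscle miRNAs, the last 2 highest in irradiated replicates 2 and 3. The erythroid list minus the stromal list changed by 0.58 (95% interval −0.96 to 2.12). Whether the miRNAs of other cell types rose alike is therefore not settled by these medians. Changes of expression within cells stay open, as no cell counts were used here, and the larger decrease of miR-181a-1-3p than of miR-181a-2-3p (−3.23) is not accounted for by the share of a single cell type with fixed content, unless other cells also make miR-181a-2-3p.

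The third pattern is the increase of miR-34b and miR-34c while miR-34a-5p did not pass. A single library as the source of the increase is argued against, since the lowest log2 change of miR-34b-3p, miR-34c-3p or miR-34c-5p with any 1 library left out was 1.95. These miRNAs are also made in epithelial cells, so a higher share of epithelial cells might contribute. Their change exceeded that of the epithelial list by 1.40 (95% interval −0.22 to 3.03), which leaves this open, and by 2.13 without irradiated replicate 3 (limma adjusted p of 0.0158, against 0.163 with all libraries). Induction by p53 was not tested, as no p53 measure was used here.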
